A study of Vigna radiata with 42 samples.

How the data were processed

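The leaves of mung bean (Vigna radiata, cultivar Weilv 9) were measured by sequencing of poly(A) RNA on the DNBSEQ platform. Seedlings grew in nutrient solution and were given 100 mM NaCl. T1 seedlings had been pre-conditioned: they had already spent 24 h in 100 mM NaCl and 48 h in solution without salt before the final salt. T2 seedlings received the salt once. Leaves were taken when the final salt began (0 h), at 1, 3 and 6 h, and at 12, 24 and 48 h, which gives 14 groups of 3 libraries and 42 libraries in all.

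The submitters' processing notes name fastp 1.0.1 for trimming, HISAT2 2.2.1 for alignment, featureCounts (no version given) for counting and DESeq2 1.48.2. The genome build and the annotation are not given in the sources used here. The deposited table holds 1 value per gene and library for 28740 gene IDs, of which 26 carry a Pt and 44 an Mt prefix. The values are treated as a normalized expression signal deposited by the authors, with gene length and depth divided out. The table is called TPM, and the plan written before the data were examined assumed that unit. Its columns do not share 1 total: they sum to between 783218 and 1228250, with a geometric mean of 1000000, so a further scaling between libraries has been applied that the sources do not describe. Read counts are not part of this table. Among 1343 genes seen in 2 to 8 libraries, 91.4% of 4416 low values were whole multiples of a gene's unit (within 0.1) once each library was given its own factor, against 20.2% without. Those factors put the relative depth at 0.78 to 1.42 times the median library. Absolute depth is therefore unknown, and no counting interval or lower limit of detection is given.

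Values were compared as log2(value + 1). Changes on this scale understate the change of genes near 0. Genes with a value of at least 1 in at least 3 libraries were tested: 19753 of 28740, or 68.7%. One linear model with a mean per group was fitted with limma 3.58.1 in R 4.3.3, with the variance moderated by a robust trend over all 42 libraries. Every p-value is two-sided and adjusted by the Benjamini-Hochberg method over the 19753 genes within each contrast. A gene was called at an adjusted p under 0.05. The contrasts were T1 against T2 at 7 times, each later time against the 0 h group of its own treatment, and 6 interactions (the change in T1 minus the change in T2). F tests took all times together. Within 3 against 3 libraries only 10 splits exist, so a permutation test of a single gene could not give a p under 0.1, and the calls rest on the variance shared over genes and groups. The p-values measure spread between these libraries. The labels call them replicates, and whether each is a separate plant or a pool is not given in the sources used here.

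Correlations between responses run across genes, and genes are not independent replicates, so no p is given for them. Where the same 0 h group is subtracted on both sides of a correlation or overlap, the shared libraries raise it. For the 0 h difference against the T2 response this was measured with 100 simulations without any effect. The expected overlap of 2 lists is the product of their lengths over 19753. Depth, principal components and figures were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

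The fit was checked on simulated data: normal values with each gene's mean and SD and no group difference were drawn, and 100 expressed genes per size of change were shifted in 1 group. A log2 change of 1 was recovered for 81% of genes in T1 against T2 at 48 h, for 76% in T2 at 24 h against 0 h and for 72% in the interaction at 1 h. For a change of 2 the shares were 96%, 97% and 95%. False calls made up 4.84%, 7.49% and 3.47% of all calls. The draws were independent between genes, with 1 SD per gene in all groups and no library set apart. These shares therefore do not measure false calls in the real libraries. Random splits of those within each time gave up to 3459 genes for the interaction at 1 h.

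These alternatives were fixed before the data were examined: pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5, median-of-ratios scaling, quantile normalization, a replicate block, no robust moderation, a fit to only the groups compared, and leaving out each library. Added after the data were seen were scaling of every library to the same total, leaving out 3 libraries high in Pt signal, and letting 1 library stand for T2 at 1 h. The last, like leaving out each library, also leaves fewer libraries in a group, which by itself can lower a count. The table does not pair gene IDs with names, and 0 of the IDs matched the reference gene list (assembly Vradiata_ver6). For that reason 57 gene lists written before the data were examined, which name genes by product, were not run, and no gene function is given. The rule for printing single genes, also set then, ordered called genes by log2 change if their mean was at least 5 in the higher group and the libraries of both groups did not overlap. Of the 3357 genes that passed it for T2 at 24 h, the 2 highest and the 2 lowest are printed; that comparison was picked afterwards. No library was left out.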

Results

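Leaf transcriptomes were followed in mung bean seedlings over 48 h of 100 mM NaCl. T1 seedlings had met salt before, for 24 h, and had then recovered for 48 h. T2 seedlings met it once. Each of 7 times from 0 to 48 h has 3 libraries per treatment. The series has no unsalted plants after 0 h, so a change from 0 h holds the effect of salt together with those of plant age and time of day. Samples at 24 and 48 h share the time of day with 0 h. Relative depth ran from 0.78 to 1.42 times the median library. Genes carry IDs only, so groups of genes are described by their course.

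The libraries were ordered mainly by time. The first 2 principal components held 27.1% and 19.2% of the variance, with the 12 h libraries at one end of the first. The 10 genes with the highest mean over all libraries held 15.6% of the signal at 0 h, 7.75% at 12 h and 12.8% at 48 h in T2, and 16.7%, 9.32% and 13.3% in T1. T1 0 h replicate 2 stood apart from its group. Its mean correlation was 0.923 with the other T1 0 h libraries and 0.970 with the T2 0 h libraries. In 6 libraries the mean correlation was higher with another group than with their own: all 3 at T1 0 h, 1 at T1 3 h, 1 at T1 6 h and T2 1 h replicate 2. For T1 0 h replicates 1 and 3 this came from replicate 2 in their group, since their r with each other was 0.984. With T1 1 h, the closest other group, their means were 0.956 and 0.961.

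**Figure D1:**
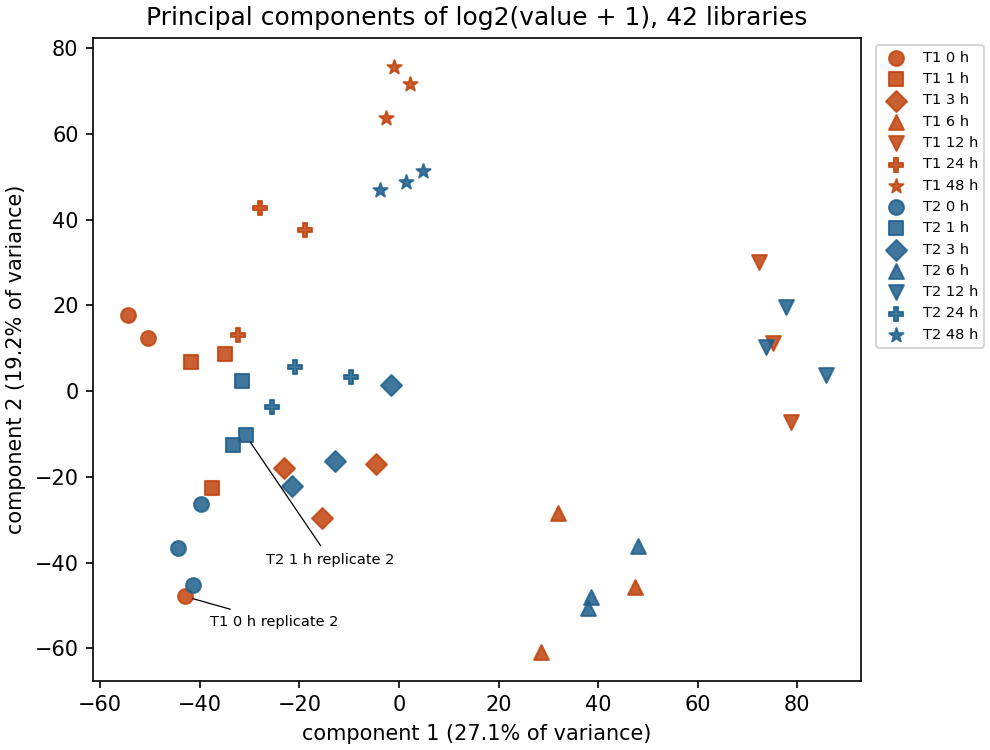
Each point is 1 of 42 libraries placed by the first 2 principal components of log2(value + 1); colour gives the treatment and shape the time. T1 0 h replicate 2 lies among the T2 0 h libraries, apart from the other T1 0 h libraries.

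What direct salt did to leaf transcripts was asked by setting each later T2 group against T2 at 0 h. Expression changed widely at every time. At 1 h, 5685 of 19753 genes had changed, and large changes were mostly increases: 1169 genes were at least 2-fold higher and 377 at least 2-fold lower. Of the 3201 genes higher at 1 h, 1112 were called higher at no other time. The number called was 5185 at 3 h, 7044 at 6 h and 9557 at 12 h, when 4688 genes were higher and 4869 lower. It was 4275 at 24 h and 8194 at 48 h. A lasting group of 1491 genes was higher at both 24 and 48 h and 1190 were lower at both, while 259 were higher and 290 lower at all 6 times.

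Single genes moved by much more. Virad09G0107700 rose from 40.8 ± 55.2 at 0 h to 8550 ± 1840 at 24 h in T2 (SD, n = 3), a log2 change of 8.62 (SE 1.08, adjusted p = 1.02e-06). Virad05G0197700 rose from 1.19 ± 0.42 to 210 ± 92.4 (log2 change 6.52, SE 0.63, adjusted p = 1.3e-08). It had already reached 165 ± 18.9 at 1 h and stood at 7.55 ± 5.93 at 12 h. Virad11G0149500 fell from 120 ± 20.4 to 2.02 ± 0.6 (log2 change -5.33, SE 0.58, adjusted p = 1.1e-07), and Virad06G0149800 fell from 358 ± 163 to 7.54 ± 1.66 (log2 change -5.29, SE 0.81, adjusted p = 2.49e-05). With 1 library left out the 4 log2 changes ran from 7.86 to 9.77, 6.19 to 6.72, -5.48 to -5.2 and -5.72 to -4.98.

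Each T2 count came from the limma fit, and the T2 time course as a whole changed 16297 genes (82.5%) in the F test. The 3 h count was 3280 without T2 3 h replicate 2 and 3401 when only the groups compared were fitted; the 24 h count was 2726 without T2 0 h replicate 3 and 2834 without T2 24 h replicate 3. The 1 h count was 3987 without T2 1 h replicate 1 and 6104 without T2 1 h replicate 2. The balance of higher and lower genes depended on scaling: at 1 h 56.3% were higher as deposited and 41.2% after quantile normalization, and at 12 h 49.1% as deposited and 81.8% with every library brought to the same total.

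**Figure D2:**
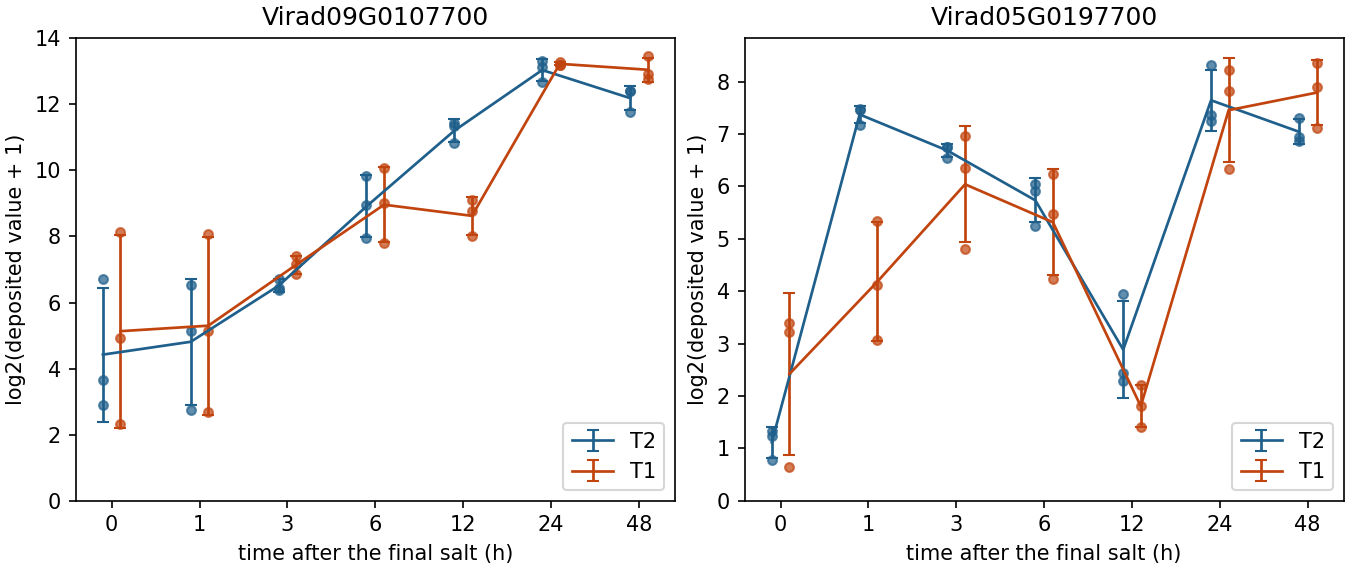
Lines join the mean of log2(value + 1) at each time for 2 genes that rose by 24 h, with SD bars (n = 3) and a point per library. Virad05G0197700 was at 165 ± 18.9 in T2 and 21.1 ± 16.6 in T1 at 1 h, and both genes were high in both treatments at 24 h.

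The response of pre-conditioned plants to the second salt was measured against T1 at 0 h. At 1 h, 2181 genes had changed, 1478 higher and 703 lower. Changes then spread to 5139 genes at 3 h, 8898 at 6 h and 8238 at 12 h, stood at 4017 at 24 h, and reached 9829 at 48 h, with 5609 genes higher and 4220 lower. Virad09G0107700 rose in T1 as well, from 106 ± 154 to 9570 ± 329 at 24 h (SD, n = 3; log2 change 8.09, but 6.68 without T1 0 h replicate 1 and 9.6 without T1 0 h replicate 2). Virad05G0197700 rose by a log2 change of 5.03, and Virad11G0149500 and Virad06G0149800 had changes of -4.63 and -4.06. Genes higher at both 24 and 48 h numbered 1609, and 822 of them were among the 1491 of T2 (121 expected without relation); of the 1247 lower at both, 678 were among the 1190 of T2 (75.1 expected).

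The T1 course changed 16458 genes (83.3%) in the F test. T1 0 h replicate 2 belongs to the 0 h group of each of these contrasts. A fit to only the groups compared gave 248, 1059, 4272, 4984, 251 and 5612 genes from 1 to 48 h, and adjusted p = 0.0554 for Virad09G0107700 at 24 h. The 1 h count was 1326 without T1 1 h replicate 3. The 24 h count was 2293 without T1 24 h replicate 1, a library high in Pt signal, and 2129 without the 3 such libraries. At 12 h, 13214 genes were called with every library brought to the same total.

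**Figure D3:**
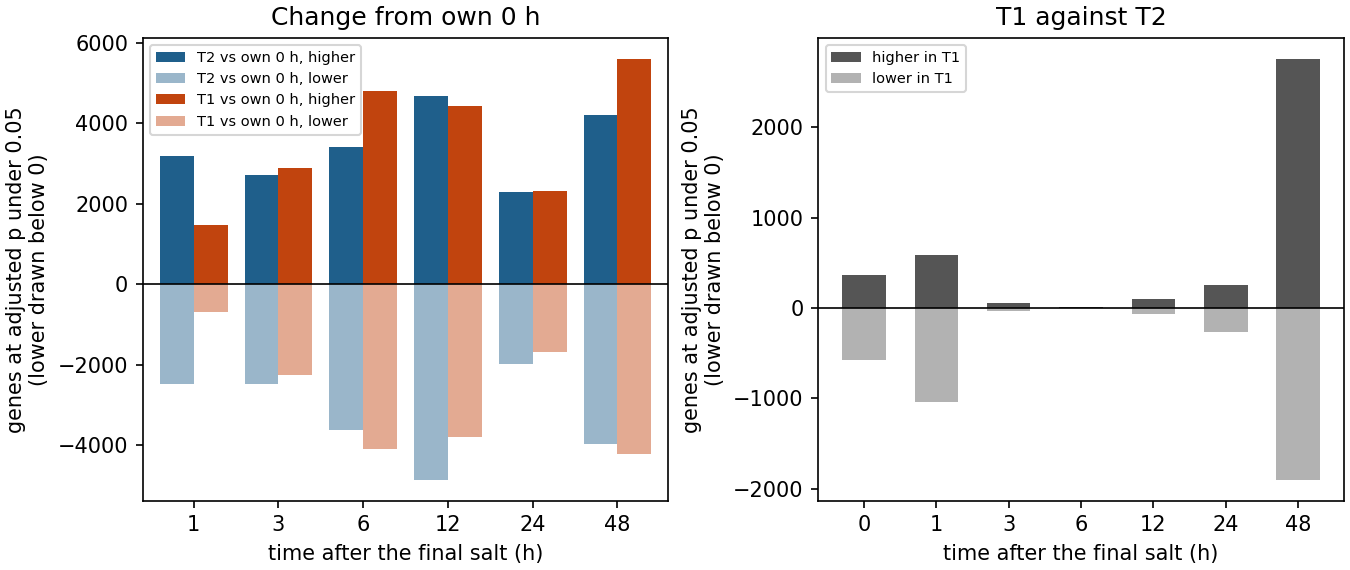
Bars count genes at an adjusted p under 0.05, higher above 0 and lower below, against time; the left panel sets each treatment against its own 0 h, and the right panel sets T1 against T2. With all libraries the right panel is tallest at 48 h, with 2756 genes higher and 1900 lower in T1.

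Whether prior salt altered the response was asked by comparing the T1 and T2 changes gene by gene. Genes called in both responses mostly moved the same way. Of the genes higher in T1 at 1 h, 1114 were higher in T2 and 5 lower; at 12 h, 3408 genes were higher in both and 3127 lower in both. Across genes, Pearson's r between the 2 responses was 0.637 at 1 h, 0.641 at 3 h, 0.850 at 6 h, 0.881 at 12 h, 0.812 at 24 h and 0.767 at 48 h, and Spearman's rho was 0.508, 0.542, 0.765, 0.799, 0.758 and 0.684. A line through the origin was fitted by total least squares, which treats both responses alike and is not a regression of T1 on T2. Its slope, T1 over T2, was 0.583 at 1 h and between 0.909 and 1.16 at the later times. Without T1 0 h replicate 2 the correlation was 0.433 at 3 h and 0.686 at 24 h, and without T2 1 h replicate 2 it was 0.507 at 1 h.

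With all libraries, an interaction was called in 357 genes at 1 h. In 230 of these the T1 change was the lower one: 221 had risen in T2 and 88 in T1, with median log2 changes of 1.43 and 0.23. Virad05G0197700 is among them: it stood at 165 ± 18.9 in T2 and 21.1 ± 16.6 in T1 (SD, n = 3), with a difference in response of -4.50 (SE 0.89, adjusted p = 0.00725). Part of this came from 0 h, where it was at 1.19 ± 0.42 in T2 and 6.13 ± 4.86 in T1. That difference (log2 1.3) was not called. In the other 127 genes, 104 had fallen in T2, with medians of -0.82 in T2 and 0.07 in T1. At 48 h an interaction was called in 1656 genes. T1 had the higher change in 1155, with medians of 0.65 in T1 and -0.09 in T2, and the lower change in 501, with medians of -0.59 and 0.27. Counts were 156 at 3 h, 5 at 6 h and 29 at 12 h. The 0 h difference is part of each interaction: at 1, 3, 6, 12 and 48 h, 85, 87, 2, 8 and 233 of the genes differed between T1 and T2 at 0 h, and 244, 30, 2, 20 and 1221 at the time itself. At 24 h limma called 0 genes, with 1008 at an unadjusted p under 0.05. Over all times the interaction was called in 3147 genes (15.9%).

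Interaction counts moved widely when 1 library was left out. The 1 h count was 1489 without T1 0 h replicate 2, 1181 without T2 1 h replicate 2, and between 110 (without T1 1 h replicate 1) and 218 (without T1 0 h replicate 3) without T1 0 h replicate 1, T2 0 h replicates 2 or 3, or T2 1 h replicates 1 or 3; it was 3 in a fit to only the groups compared, 232 with a pseudocount of 0.1, and 61 with T2 1 h represented by replicate 2 alone. The 48 h count was 3737 without T1 0 h replicate 2, 490 without T1 48 h replicate 1, 867 without T2 48 h replicate 1, 936 without T2 0 h replicate 3, 968 without T1 48 h replicate 2, 1039 without T1 0 h replicate 1, and 193 in a fit to only the groups compared. The count over all times was 6352 without T1 0 h replicate 2, 1838 without T1 48 h replicate 1 and 2016 without T2 48 h replicate 1. The counts at 3, 6 and 12 h were 3207, 2833 and 1457 without T1 0 h replicate 2, so the order of the times by count depends on that library.

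T1 and T2 were also compared at 0 h, after the recovery of T1 and before the final salt. What remained of the earlier salt cannot be told apart here from plant age and handling. Whether the treatments were matched in these is not given in the sources used here. T1 and T2 differed in 939 genes, 366 higher and 573 lower in T1, and 239 of these differed at least 2-fold. Its correlation across genes with the T2 change was 0.189 at 1 h, 0.268 at 3 h, -0.0821 at 6 h, 0.177 at 12 h, 0.248 at 24 h and 0.33 at 48 h (Spearman's rho 0.235, 0.204, -0.0434, 0.273, 0.279 and 0.388). The T2 0 h libraries enter both sides, which alone gave a mean r of 0.502 in simulations without any effect. The real T2 change adds spread that lowers r, so the 2 kinds of r are not comparable. The covariance, 0.0308 in those simulations, was 0.0494, 0.0674, -0.0251, 0.0702, 0.0547 and 0.105 from 1 to 48 h. It lay above the simulated value except at 6 h. These covariances all use the same 0 h libraries and their spread was not tested. They do not by themselves show that the difference went the way of direct salt. Of the genes lower at 0 h, 126 were also lower in T1 at 1 h (30.2 expected), and of those higher, 58 were also higher (10.9 expected).

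This comparison moved widely when 1 library was left out, which by itself can lower a count. It gave 5522 genes without T1 0 h replicate 2, 33 without T1 0 h replicate 1, 45 without T1 0 h replicate 3, and 476, 524 and 47 without T2 0 h replicates 1, 2 and 3. In a fit to only these 2 groups limma called 0 genes, with 1845 at an unadjusted p under 0.05, and the share of called genes that were higher in T1 was 39% as deposited but 53.4% after median-of-ratios scaling. The 6 h correlation was 0.00833 without T2 0 h replicate 1.

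At 1 h of salt T1 and T2 differed in 1628 genes, of which 586 were higher and 1042 lower in T1. Of those that differed at least 2-fold, 357 were lower in T1 and 72 higher. Genes of the early direct response were among them: of the 738 genes that had risen at least 2-fold in T2 by 3 h, 147 were lower in T1 at 1 h and 6 higher. The median difference of the 738 was -0.31 on the log2 scale, with quartiles of -0.75 and 0.06, and 71.3% lay below 0, against 56.6% of all genes. The 658 genes that had fallen at least 2-fold in T2 by 3 h hardly differed in level, with a median of 0.04 (-0.04 over all genes), 46.7% below 0, 49 higher in T1 and 12 lower. This set was already lower in T1 at 0 h, with a median difference of -0.29. Genes chosen by a 2-fold change in T1 by 3 h had medians of -0.38 (823 raised) and 0.29 (421 lowered). Both differences were already present at 0 h, with medians of -0.39 and 0.35, against 0.04 for the 738 genes. They therefore do not show a weaker response of T1 at 1 h. The choice itself uses the T1 0 h libraries, which by itself moves these sets at 0 h. Virad05G0197700 differed by -3.19 (SE 0.63, adjusted p = 0.00124). The T2 libraries at 1 h were uneven, with 18913 and 18636 genes at a value of at least 1 in replicates 1 and 3 and 17663 in replicate 2.

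The 1 h count was 771 without T2 1 h replicate 1, 1060 without T1 1 h replicate 1, 1016 without T1 1 h replicate 3, 482 with T2 represented by replicate 2 alone, and 241 in a fit to only the 2 groups. Which direction held more genes depended on scaling: 36.0% were higher in T1 as deposited and 55.8% after quantile normalization. The median of the 738 early genes stayed below 0 under each scaling, at -0.24 after quantile normalization.

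From 3 to 24 h few genes were called between T1 and T2. There were 88 at 3 h, 11 at 6 h, 165 at 12 h and 530 at 24 h, with 259 higher and 271 lower in T1 at 24 h. At an unadjusted p under 0.05 limma gave 2989, 2442, 1838 and 3519 genes. Few calls therefore do not show that the treatments were alike. Virad11G0149500, which fell in both treatments by 24 h, was higher in T1 at 12 h, at 79.4 ± 55.1 against 10.1 ± 4.1 in T2 (SD, n = 3; log2 difference 2.60, SE 0.58, adjusted p = 0.0203). Of the 259 genes higher at 24 h, 115 were also higher at 48 h (36.1 expected), and of the 271 lower, 81 were also lower (26.1 expected).

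These counts moved widely when 1 library was left out. That also leaves fewer libraries in a group, which by itself can lower a count. The 24 h count was 88 without T1 24 h replicate 1, 172 without T2 24 h replicate 1, 152 without T2 24 h replicate 2, and 39 without the 3 libraries high in Pt signal, which held 5.38% (T1 24 h replicate 1), 2.50% (T2 24 h replicate 2) and 2.08% (T2 12 h replicate 3) of signal there. The 12 h count was 52 and 49 without T1 12 h replicates 2 and 3, and 79 and 51 without T2 12 h replicates 2 and 3. At 3 h it was 27 and 3 without T1 3 h replicates 1 and 2, and 47 and 12 without T2 3 h replicates 1 and 3. At 6 h it was 1, 3 and 81 without T1 6 h replicates 1, 2 and 3, and 0 and 1 without T2 6 h replicates 1 and 3. In fits to only the groups compared limma called 0 genes at 3 h and at 6 h, with 2416 and 1825 at an unadjusted p under 0.05.

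After 48 h of salt pre-conditioned and directly salted plants differed in 4656 genes, more than at 1 to 24 h; at 0 h the count was 939, or 5522 without T1 0 h replicate 2. Of the 4656, 2756 were higher and 1900 lower in T1, and 481 were at least 2-fold higher and 252 at least 2-fold lower. The genes higher in T1 included 623 that had risen in T2 at 24 h (319 expected) and 117 that had fallen (278 expected); those lower in T1 included 441 that had fallen (192 expected) and 103 that had risen (220 expected). They overlapped the T2 response at 1 h as well, with 931 genes higher in both (447 expected) and 531 lower in both (239 expected). Across genes the 48 h difference had r = 0.247 with the T2 change from 0 to 1 h, 0.397 to 3 h, 0.137 to 6 h, 0.0806 to 12 h and 0.219 to 24 h (rho 0.285, 0.340, 0.168, 0.113 and 0.271), which share no library with it. It had r = 0.27 with the 0 h difference. Of all genes tested, 6612 (33.5%) differed between T1 and T2 at some time in the F test.

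The 48 h count was 2744 without T1 48 h replicate 1 and 2894 without T1 48 h replicate 2. The count over all times was 9984 without T1 0 h replicate 2.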

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

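In the paragraphs on explanations, the tests of a swap, of a wrong label, of T1 lying further along, and of scaling, of spread at 0 h and of the early genes in other libraries for the 1 h response, were chosen after the results were seen. For every comparison of 3 against 3 libraries the 10 splits are too few to give a share under 0.05.

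A difference between the treatments in their change from 0 h, each by its own test, brought these results here. The interaction was called in 357 genes at 1 h, 156 at 3 h, 5 at 6 h, 29 at 12 h and 1656 at 48 h. Of 100 splits of the same libraries, 8, 5, 14, 5 and 6 gave as many, with up to 3459, 1497, 2598, 284 and 4973 genes, so chance is not excluded for any of these counts. At 24 h limma called 0 genes, 1008 at an unadjusted p under 0.05; all 100 splits gave as many, up to 3724. Over all times the interaction was called in 3147 genes. Only 1 of 100 splits, the real one, gave as many, which is the lowest share these splits can give, and the highest other gave 2804. Chance is argued against with all libraries, but by a narrow margin. The count was 1838 without T1 48 h replicate 1 and 2016 without T2 48 h replicate 1, and splits were not drawn again without them. Chance is also argued against, by wider margins, for the F tests of T1 against T2 at any time (6612 genes, highest other 2387), of time in T1 (16458, highest other 4604) and of time in T2 (16297, highest other 2842).

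T1 0 h replicate 2 lies with the T2 0 h libraries: on an axis from the T2 0 h mean at 0 to the other T1 0 h libraries at 1, its place is -0.0916. A swap needs a T2 0 h library in its place, and the highest of these lay at 0.197. Lower depth is argued against by the well-expressed genes, those with a mean of at least 50, where its place is -0.0734. A wrong label cannot be told apart from a plant with little left of the earlier salt: its mean correlation with the T2 0 h libraries is 0.970, just under their lowest with each other, 0.980, and above the lowest between replicates in the 13 other groups, 0.962. At 0 h, 3 of 10 splits gave as many as the 939 genes found, and the highest other gave 3636 by exchanging this library with T2 0 h replicate 1, which points to a structure of the samples that the labels do not follow.

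T1 and T2 differ in more genes at 48 h, 4656, than at 1 to 24 h, where the highest count is 1628; at 0 h the count is 939, but 5522 without T1 0 h replicate 2, so 48 h ranks above 0 h only with that library. Scaling between libraries is argued against, since the lowest of 3 other scalings gave 4058, and so is a single 48 h library, since leaving out each gave at least 2744. Whether T1 plants lay further along the course of directly salted plants stays open: the 48 h difference had r = 0.219 with the T2 change from 0 to 24 h, but r = 0.247 and 0.397 with the changes to 1 and 3 h, so it does not favour the later course over salt responses in general. Plant age, which may differ between T1 and T2, was not tested. The real split gave 4656 genes and the highest other 74.

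The response at 1 h is smaller in T1, 2181 genes against 5685. In level at 1 h, genes raised early in T2 were lower in T1 (median -0.31) and those lowered early in T2 hardly differed (0.04, all genes -0.04). In change from 0 h both sets moved less in T1, with medians of 0.66 against 1.02 and -0.44 against -0.76. Sets chosen by their change in T1 by 3 h did not: T1 had 0.84 against 0.75 in T2, and -0.74 against -0.70. Each choice shares 0 h libraries with the change of its own treatment, which favours that treatment. Scaling is argued against: 3 other scalings gave 1810 to 2245 genes in T1 and 4889 to 6208 in T2, and the raised genes' median nearest to 0, under quantile normalization, was -0.24 (-0.32 to -0.20 with 1 library left out; all genes 0.03). Other tissue in T2 1 h replicates 1 and 3 is argued against for the raised genes only, by tests with limits. In 5 other libraries the 187 genes high in those replicates exceeded the rest of the group by log2 1.96 to 2.41. In replicates 1 and 3 this excess was 1.65 and 1.51, but each was set against a mean that holds the other. Their level, 12.9, was nearly reached in T1 0 h replicate 2 (12.6), while the remaining libraries had 6.92 to 8.76. In these 5 libraries, 732 raised genes outside that set had a median excess of at most 0.06, and of -0.23 in T1 0 h replicate 2. Their median T1 minus T2 difference with T2 1 h replicate 2 alone, a single library and all 738 raised genes, was -0.31. For the counts other tissue stays open. A T2 group of replicate 2 alone also has fewer libraries, so its counts cannot be set beside those from 3. Spread among the T1 0 h libraries also stays open for the counts, with 3240 genes in T1 without T1 0 h replicate 2 against 4236 to 5255 in T2 with 1 T2 0 h library left out (the bound first written set unequal numbers of libraries against each other). Pre-conditioning is the candidate explanation that the design names, with plant age and handling untested beside it; the direct comparison at 1 h gave 1628 genes and 721 in the highest other split, T2 at 1 h gave 5685 and 270, and T1 at 1 h gave 2181 and 1887.

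For the remaining comparisons, the real split was the 1 of 10 with as many genes except at 6 h. T1 against T2 gave 88 genes at 3 h (highest other 43), 11 at 6 h (2 splits with as many, highest other 87), 165 at 12 h (17) and 530 at 24 h (1). T2 gave 5185 at 3 h (1), 7044 at 6 h (1), 9557 at 12 h (0), 4275 at 24 h (6) and 8194 at 48 h (1). T1 gave 5139 at 3 h (2479), 8898 at 6 h (4663), 8238 at 12 h (2150), 4017 at 24 h (1448) and 9829 at 48 h (934), and each of these highest others exchanged T1 0 h replicate 2.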

How the results depend on the processing

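Scaling to the same total, leaving out the Pt-high libraries and T2 1 h as 1 library were chosen after seeing the data; the cause of the changes was not tested unless given. No count moved by over 1.5 times with a pseudocount of 0.5, without robust moderation or with a replicate block. The replicate block gave 0 of 29 counts moved; whether numbers pair libraries was checked, and residuals of libraries with the same number had a mean correlation of -0.0154, against 0.00776 for other numbers. Tests of gene lists were not run, since no IDs have names. The 4 genes printed kept direction and call in T2 at 24 h under each alternative, leaving out each library included, and so did Virad09G0107700 in T1 24 h vs T1 0 h (adjusted p from 2.15e-07 to 9.35e-05) except in a fit to only the groups compared (adjusted p = 0.0554). Without counts, depth sets no stated limit.

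A pseudocount of 0.1 gave 232, 96 and 16 interaction genes at 1, 3 and 12 h. With no filter T1 and T2 differed in 1 gene at 6 h, and the 24 h interaction had 1. With a mean of at least 5, T1 and T2 differed in 91 genes at 12 h and 341 at 24 h, and the 12 h interaction had 15 (fewer genes tested). Median-of-ratios scaling gave 1 gene for T1 against T2 at 6 h and 0 for the 6 h interaction (limma, 2930 unadjusted). Quantile normalization gave 1 at 6 h.

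Scaling to the same total gave 251 and 6 genes for T1 against T2 at 3 and 6 h, 13214 for T1 at 12 h, and 35 and 3 for the interaction at 3 and 6 h. By construction it moved the median of all genes: to 0.23, 0.39 and 0.205 in T2 at 6, 12 and 48 h, to 0.27, 0.49 and 0.29 in T1, and to -0.15 for T1 minus T2 at 1 h. Changes named elsewhere are on the deposited scale.

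A fit to only the groups compared, whose variance rests on fewer libraries, gave for T1 against T2 0, 241, 0, 0 and 98 genes from 0 to 12 h; 3401 for T2 at 3 h; 248, 1059, 4272, 4984, 251 and 5612 for T1; and 3, 0, 1, 0 and 193 for the interaction at 1, 3, 6, 12 and 48 h. The counts of 0 had 1845, 2416, 1825, 2002 and 1793 genes at an unadjusted p under 0.05. Without the Pt-high libraries, T1 and T2 differed in 53 and 39 genes at 12 and 24 h, T1 at 24 h had 2129 and the 12 h interaction 8. With T2 1 h as 1 library, counts at 1 h were 482 for T1 against T2, 2599 for T2 and 61 for the interaction.

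Leaving out each library gave these ranges. For T1 against T2: 33 to 5522 at 0 h, 771 to 2176 at 1 h, 3 to 69 at 3 h, 0 to 81 at 6 h, 49 to 179 at 12 h, 88 to 543 at 24 h and 2744 to 4802 at 48 h, and 5201 to 9984 at any time. For T2: 3280 to 4877 at 3 h and 2726 to 3864 at 24 h. For T1: 1326 to 3240 at 1 h and 2293 to 4433 at 24 h. For the interaction: 110 to 1489, 16 to 3207, 0 to 2833, 0 to 1457, 0 to 49 and 490 to 3737 from 1 to 48 h, and 1838 to 6352 over all times; each highest value was without T1 0 h replicate 2. The correlation of responses ran from 0.686 to 0.82 at 24 h, from 0.433 to 0.71 at 3 h and from 0.507 to 0.689 at 1 h. That of the 0 h difference with the T2 change at 6 h ran from -0.115 to 0.00833 and so reversed.

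The share of called genes that were higher also moved under the 3 other scalings. At 6 h it rests on few genes. T1 against T2 had 11 called there as deposited and at most 6 under the others, and the interaction 5 and at most 4. These 6 h shares therefore do not show an effect of scaling. Shifts of over 10 percentage points were as follows. Under median-of-ratios scaling it was 53.4% rather than 39% for T1 against T2 at 0 h, 0% rather than 72.7% at 6 h, and 47.6% rather than 60.9% for the 3 h interaction. Under quantile normalization it was 55.8% rather than 36.0% at 1 h, 47.8% rather than 63.6% at 3 h and 0% rather than 72.7% at 6 h; 41.2% rather than 56.3% for T2 at 1 h; 46.2% rather than 56.2% for T1 at 3 h; and 50% rather than 80% and 57.5% rather than 69.7% for the interaction at 6 and 48 h. Scaling to the same total gave 17.1%, 14%, 12%, 50% and 27.1% for T1 against T2 at 0, 1, 3, 6 and 24 h (39%, 36.0%, 63.6%, 72.7% and 48.9% as deposited). For T2 it gave 68.8%, 67.2%, 76.9%, 81.8%, 70.2% and 76.3% from 1 to 48 h (56.3%, 52.2%, 48.6%, 49.1%, 53.4% and 51.4%). For T1 from 3 to 48 h it gave 67.4%, 76.3%, 87.2%, 71.3% and 79.1% (56.2%, 53.9%, 53.9%, 57.8% and 57.1%), and for the interaction at 3, 6 and 12 h 71.4%, 66.7% and 74.4% (60.9%, 80% and 58.6%).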

Other observations

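Both tests below were chosen after the result was seen.

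The time of the largest change is described for each treatment, with 12 h the commonest in both. Among genes that changed at least 2-fold at some time, the largest change came at 1 h for 14.9% of 6064 genes in T2 and 4.03% of 6378 in T1, at 6 h for 16% and 24.8%, at 12 h for 39.4% and 32.6%, and at 48 h for 19.3% and 30.9%. The difference between these shares was not tested. Genes called higher at all 6 times numbered 259 in T2 and 147 in T1, with 62 in both (1.93 expected), and genes lower at all 6 numbered 290 and 155, with 82 in both (2.28 expected). Of genes higher at 1 h and at no other time, there were 1112 in T2 and 201 in T1, with 141 in both (11.3 expected).

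A set of 187 genes was high in T2 1 h replicates 1 and 3, at 0.554% and 0.498% of the signal, but not in replicate 2, at 0.0308%. Their median level, 12.9 in the mean of those 2 libraries, was nearly reached in T1 0 h replicate 2, at 12.6, and partly in T1 24 h replicate 2 (8.76), T1 3 h replicate 1 (8.22) and T2 12 h replicate 1 (7.68). Deeper sequencing is argued against: the median of their median levels over the 10 deepest other libraries was 1.04. The genes may come from cells or tissue of another kind caught in single libraries, since their deviations in the other libraries had a mean correlation of 0.525, against at most 0.0376 in 1000 random sets of matched level. A program shared within leaf cells would give the same value, and no cell type was tested. Of the 1042 genes lower in T1 at 1 h, 15 belong to the set. The set was picked for a wide spread within T2 at 1 h, which by itself makes such calls less likely. This overlap therefore does not measure how far the set bears on the results at 1 h. Against their own 0 h, 44 of the 187 genes were called higher in T2 at 1 h and 0 in T1.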
